A study of Homo sapiens with 9 samples.

How the data were processed

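RNA was measured in LAN-5, an established human neuroblastoma cell line, on 9 Affymetrix 1-colour oligonucleotide arrays hybridised with biotin-labelled cRNA. Per the labels, 3 arrays came from untreated cells, 3 from cells given the S100B protein at 0.5 nM and 3 from cells given it at 5 µM, and the series design describes the 3 arrays of a group as biological replicates. Groups and replicate numbers were taken from the sample titles. The length of the treatment and any vehicle given to the untreated cells are not given in the sources used here.

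The deposited values are on a log2 scale, 1 value per probe set and array, and GCRMA is the tool named per the submitters' processing notes, with no version or setting given there. GCRMA corrects background with probe sequence, normalises between arrays and summarises the probes of a probe set. Differences near the background may be compressed, which would understate fold changes of dim probe sets, and this was not tested here. That the scale is log2 was read from the values, which ran from 4.37 to 14.5 with array medians of 6.60 to 6.64. The scanner intensities were not used here, so signal over background per probe set could not be assessed. The number of arrays limits the precision.

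The table held 8793 probe sets. The 47 manufacturer's control probe sets were taken out, and of the remaining 8746 the dimmest by the mean over all 9 arrays were left out, which removed 2916 probe sets with a mean at or below 5.95 and left 5830. Gene names came from the platform annotation supplied with the values, with symbols updated by Entrez identifier through a RefSeq gene table. Of the 8746 probe sets, 7840 had 1 gene symbol, 388 had several and 518 had no entry. Of the 7840, 7838 matched the RefSeq table, and the 7840 covered 7713 genes. Probe sets with several symbols or no entry were tested and are not named by gene. No genomic coordinates are given, since no build is named for the arrays.

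Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) to all 9 arrays at once, with 1 factor of 3 groups and no covariate. The pooled fit had a prior of 4.55 degrees of freedom and a prior SD of 0.0842 log2. Each of the 3 comparisons was adjusted by the Benjamini-Hochberg method over 5830 probe sets, and an adjusted p under 0.05 was the threshold. Standard errors of log2 fold changes are those of the moderated fit, and values written with SD are over the 3 arrays of a group. An exact permutation test of 3 arrays against 3 cannot go below a p of 0.1, so single genes rest on limma's pooled spread. The median half-width of the 95% interval of a fold change was 0.156 log2.

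The test, the filter, the gene lists and the rule for naming genes were set before the data were examined. There were 28 lists from textbook knowledge: S100 family and S100B receptors, NF-kB target genes, immediate early genes, MAPK feedback genes, calcium handling genes, pro-apoptotic genes, pro-survival genes, p53 target genes, NRF2 and antioxidant genes, unfolded protein and amino acid stress genes, heat shock genes, DNA replication genes, mitotic genes, neurite and synapse genes, noradrenergic neuroblastoma genes, amyloid and tau genes, interferon response genes, cholesterol synthesis genes, glycolysis and hypoxia genes, oxidative phosphorylation genes, cytosolic ribosomal protein genes, proteasome genes, RNA splicing factor genes, metallothionein genes, and markers of mesenchymal and Schwann-like cells, of astrocytes and oligodendrocytes, of leukocytes and of epithelium. They hold 745 genes, of which 611 had a probe set with 1 symbol and 485 lay above the filter. Of the 745, 32 stand in more than 1 list. Each list was tested with camera at a preset correlation of 0.01, with the probe set of highest mean for each gene, over 5147 genes, and adjusted over all lists and comparisons. A list with under 5 measured members was described and not tested, which applied to 2 lists. Camera with an estimated correlation and fry were run beside it. The 95% interval of a list is that of the difference in the mean of its genes per array.

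Named genes follow a rule applied to probe sets with 1 symbol, 1 per gene with the smallest p. In each comparison they are up to 12 with the largest rise and 12 with the largest fall among those past the threshold whose arrays do not overlap between groups. Where fewer than 5 genes passed, the 10 with the smallest p are named. Of each list, up to 4 members past the threshold are named, or the 1 with the smallest p. AGER, S100B, APP, FGFR1 and MYCN are named wherever measured, and up to 8 genes changed at both doses would have been. Genes named outside the rule are marked as chosen after their values were seen. Members of the lists added under Other observations were also named after their values were seen.

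The procedure was tested on simulated data for 5 µM against untreated, with 200 of 5830 probe sets changed and the members of 1 gene list shifted besides. It called 87.9% of the probe sets changed by 0.5 log2 and 98.0% of those changed by 1 log2, and 8 of the 5607 probe sets left unchanged. At 0.5 nM, where no change was simulated, 0 were called. The noise was drawn independently for each probe set. With many probe sets changed, the adjusted threshold is easier to pass than with few. The shares called may therefore overstate those in the real data. Alternatives were another filter or none, quantile normalization, median centring, a trended and robust prior, a fit of only the 2 groups compared, a replicate block, array weights, a plain unmoderated test, a 2-fold limit, counting genes, and leaving out each array in turn. A fit without replicate 3 of every group and a fit with the 3'/5' signal ratio of the ACTB and GAPDH controls as a covariate were added after the data were seen. The unmoderated test also used only the arrays of the 2 groups compared. Figures were drawn with matplotlib 3.10.9.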

Results

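Gene expression was measured in LAN-5 human neuroblastoma cells, a neuroblast-like line, after exposure to extracellular S100B, a calcium-binding protein that astrocytes secrete and that binds the receptor RAGE. There were 3 arrays from untreated cells, 3 from cells at 0.5 nM and 3 from cells at 5 µM, and 5830 probe sets were compared on the log2 scale. Arrays of 1 group correlated at 0.996 to 0.998 across probe sets, and arrays of different groups at 0.996 to 0.998. The SD of the log2 difference between a pair of arrays was 0.108 to 0.168 within groups and 0.119 to 0.164 between groups. The 3' minus 5' signal of the ACTB control, a measure of RNA integrity, differed by -0.0048 log2 between the 5 µM and untreated means, and that of the GAPDH control by 0.0409, against SDs within the untreated group of 0.144 and 0.0362.

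The first question was which transcripts the micromolar dose changed. Genes of cholesterol synthesis fell in cells given 5 µM S100B. HMGCS1, which makes the HMG-CoA used for mevalonate, went from 8.91 ± 0.23 log2 (SD, n = 3) in untreated cells to 7.76 ± 0.04 (SD, n = 3), a change of -1.14 ± 0.12 (SE) or 45.2% of the untreated level, with limma's adjusted p = 0.00217. MSMO1, a sterol methyl oxidase, fell by 0.89 ± 0.09 (SE) to 54.0% of untreated (adjusted p = 0.00217). DHCR7, which catalyses the last step of one route to cholesterol, changed by -0.66 ± 0.09 (adjusted p = 0.0161) and the squalene epoxidase SQLE by -0.66 ± 0.09 (adjusted p = 0.0154). INSIG1, the endoplasmic reticulum protein that retains the sterol sensor complex and is itself sterol-regulated, changed by -0.64 ± 0.09 (adjusted p = 0.0162).

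In the cholesterol synthesis list, 16 of 24 genes were measured, and 9 fell, 0 rose and the others did not pass over all probe sets. Adjusted over the list alone, 12 fell. Besides the genes above, lanosterol synthase LSS changed by -0.57 ± 0.08, the isomerase IDI1 by -0.56 ± 0.08, farnesyl diphosphate synthase FDPS by -0.51 ± 0.07 and the desaturase SC5D by -0.46 ± 0.08 (SE, n = 3 per group), with limma's adjusted p of 0.0162, 0.0154 and 0.0363 for IDI1, FDPS and SC5D. The members that passed only over the list alone were MVD at -0.40 ± 0.07, NSDHL at -0.31 ± 0.07 and EBP at -0.20 ± 0.08. The members that passed in neither way were MVK at -0.10, the regulators SREBF2 at -0.09 and SREBF1 at 0.16, and PMVK at 0.05. These 7 members from MVD on were named after their values were seen. The list mean differed from untreated by -0.44 log2 with a 95% interval of -0.53 to -0.34, and all 3 treated arrays lay below all 3 untreated arrays. Camera gave an adjusted p of 1.21e-20 for the list, with an adjusted p = 0.03 with an estimated correlation.

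**Figure D1:**
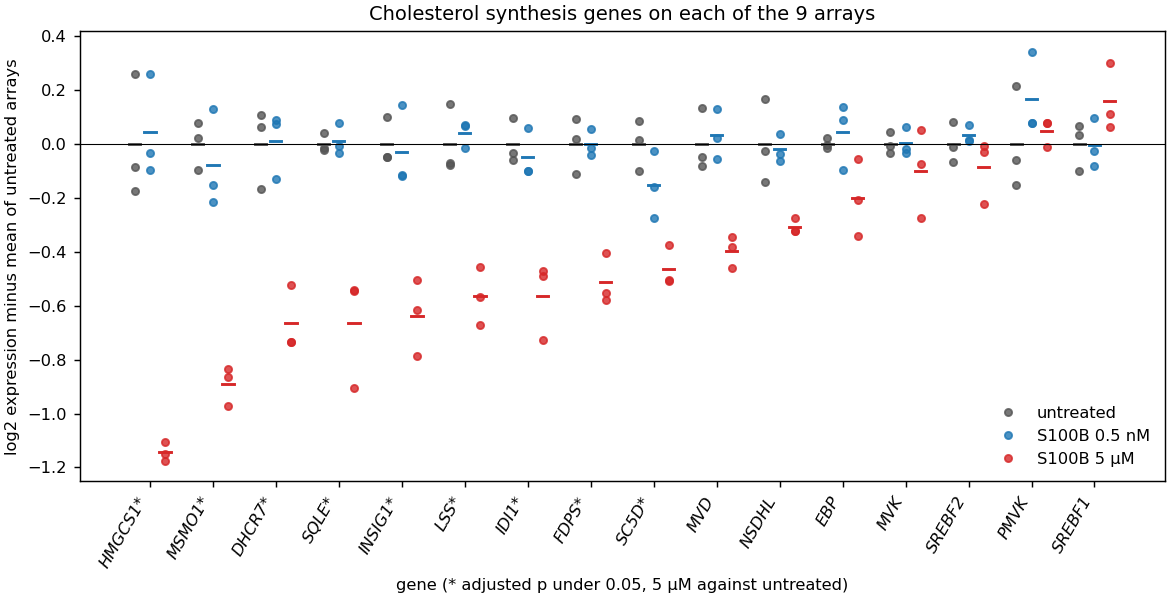
Expression of the 16 measured cholesterol synthesis genes on each of the 9 arrays, as log2 expression minus the mean of the untreated arrays (vertical axis), by gene (horizontal axis), with untreated cells in grey, 0.5 nM in blue and 5 µM in red. Points are arrays, short lines are group means, and an asterisk marks the 9 genes with an adjusted p under 0.05 for 5 µM against untreated. HMGCS1 lies lowest at 5 µM, at -1.14.

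Outside the list, the other changes at 5 µM were also falls. HSD17B7, a ketosteroid reductase that also acts in cholesterol synthesis but was not in the list, changed by -0.65 ± 0.07 (adjusted p = 0.0033). CRABP2, which binds retinoic acid, changed by -0.57 ± 0.09 (adjusted p = 0.0314) and the muscarinic receptor CHRM3 by -0.49 ± 0.07 (adjusted p = 0.0228). PPEF1, a phosphatase with EF-hand motifs, is named after its value was seen, at -0.43 ± 0.07 (adjusted p = 0.0321). The probe sets of HSD17B7 and IDI1 are of a type that can match unrelated transcripts, and those of DHCR7, INSIG1, SC5D and PPEF1 of a type that can match more than 1 transcript. Another 4 of the changed probe sets do not have exactly 1 gene symbol in the annotation used here, at -0.85 ± 0.06, -0.73 ± 0.10, -0.45 ± 0.07 and -0.31 ± 0.05. The first of these had the smallest adjusted p of the comparison, 0.000123. The transferrin receptor TFRC, also named after its value was seen, at 0.47 ± 0.08, did not pass against untreated (adjusted p = 0.0563).

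In all, 17 probe sets fell at 5 µM and 0 rose by limma at an adjusted p under 0.05, 1 of them by 2-fold or more, and 399 had an unadjusted p under 0.05. After quantile normalization or median centring 16 passed, 1 of them higher. In 17 of the 17 the arrays of both groups did not overlap, which chance gives for 10% of probe sets and which held for 12.3% of all. Untreated replicate 1 stood apart in the mean of 9 spike-in control probe sets, at 9.01 log2 against 9.48 to 9.86 on the other arrays. The count was 6, 8 and 9 without 5 µM replicates 1, 2 and 3, 4, 7 and 4 without untreated replicates 1, 2 and 3, 3 without replicate 3 of every group, 7 in a fit of only the 2 groups and 0 with an unmoderated test. HMGCS1, MSMO1 and HSD17B7 passed in all 9 fits that left out 1 array, and the other named genes lost the threshold in at least 1 of them while each kept its direction.

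Genes of mitosis lay lower at 5 µM as a list. Of 31 measured members 0 passed over all probe sets, and 7 fell adjusted over the list alone, among them the mitotic kinase PLK1 at -0.29 ± 0.06, the cyclins CCNB2 at -0.24 ± 0.06 and CCNA2 at -0.25 ± 0.06, and the anaphase activator CDC20 at -0.24 ± 0.06 (SE, n = 3 per group). The list median was -0.16 and camera's adjusted p was 3.34e-07, but the adjusted p = 0.863 with an estimated correlation and 0.41 with fry. All 3 treated arrays lay below all 3 untreated arrays in the list mean. The difference was -0.145, with a 95% interval of -0.267 to -0.022 that is not adjusted for the number of lists. That interval includes the median fold change over all tested probe sets, -0.024. PLK1 itself had an adjusted p of 0.0888 over all probe sets, and the other 3 members were named after their values were seen.

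Lists that lay higher at 5 µM with camera's preset correlation were neurite and synapse genes (median 0.06, adjusted p = 0.000295), p53 target genes (median 0.05, adjusted p = 0.00753) and cytosolic ribosomal protein genes (median 0.02, adjusted p = 0.00119). With an estimated correlation their adjusted p was 0.901, 0.841 and 0.901, and 0 members rose over all probe sets or over the list alone. The members with the smallest p were the granin SCG2 at 0.20 among 35 neurite and synapse genes, the death receptor TNFRSF10B at 0.17 among 12 p53 targets, and RPL31 at 0.16 among 37 ribosomal protein genes. The ribosomal list did not pass after quantile normalization (adjusted p = 0.454) or without 5 µM replicate 1 (0.103), and the p53 list did not without 5 µM replicate 1 (0.0603) or 2 (0.0785). The neurite list did not pass without 5 µM replicate 3 (0.152), untreated replicate 2 (0.0534) or replicate 3 of every group (0.175).

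The other lists tested did not pass at 5 µM, with medians from -0.06 to 0.04 and adjusted p from 0.084 to 0.999. Among genes of S100B signalling, the list of the S100 family and S100B receptors had a median of -0.02 over 11 genes, with DIAPH1, a formin that binds RAGE, at -0.13. NF-kB targets had a median of -0.05 over 11 genes with NFKBIA, the NF-kB inhibitor, at 0.19. Immediate early genes had a median of -0.04 over 17 genes with MYC at -0.27, MAPK feedback genes -0.05 over 10 with ETV1 at -0.25, and calcium handling genes -0.02 over 18 with the calcium pump ATP2B1 at 0.16. AGER, which encodes RAGE, and S100B lay below the intensity filter, with means over all arrays of 5.94 and 5.57. Fitted without the filter, AGER changed by 0.07 ± 0.05 (adjusted p = 0.793) and S100B by -0.08 ± 0.06 (adjusted p = 0.786), and neither passed. FGFR1 was at 0.08 ± 0.09, MYCN at 0.05 ± 0.06 and APP at 0.04 ± 0.12, and none of these passed.

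Lists of cell death and stress other than p53 targets did not pass at 5 µM. Pro-apoptotic genes had a median of -0.02 over 12 genes with TNFRSF10B at 0.17, and pro-survival genes 0.0018 over 9 with BIRC5 at -0.13. The median was -0.03 for 17 NRF2 and antioxidant genes with GCLC at 0.11, 0.03 for 15 unfolded protein and amino acid stress genes with XBP1 at 0.15, -0.02 for 13 heat shock genes with DNAJB1 at -0.10, and -0.04 for 15 interferon response genes with IFITM2 at -0.17. The neuronal lists other than neurite and synapse genes did not pass either. Noradrenergic neuroblastoma genes had a median of 0.04 over 16 genes with the vesicular transporter SLC18A1 at 0.21, and amyloid and tau genes -0.02 over 18 with the secretase BACE1 at -0.18.

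Lists of growth and metabolism other than those above also did not pass at 5 µM. DNA replication genes had a median of -0.06 over 25 genes with GINS2 at -0.18. Glycolysis and hypoxia genes had a median of -0.03 over 24 genes, and adjusted over the list alone 2 rose, adrenomedullin ADM at 0.24 ± 0.07 and VEGFA at 0.35 ± 0.10, and 1 fell, the aldolase ALDOC at -0.22 ± 0.06. ADM and VEGFA were named after their values were seen. The median was -0.0048 for 38 oxidative phosphorylation genes with NDUFS1 at -0.12, -0.03 for 25 proteasome genes with PSMB2 at -0.14, and -0.0061 for 37 splicing factor genes with SNRPA at -0.18. The 4 measured metallothionein genes were too few to test as a list and had a median of -0.03 with MT2A at -0.09.

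The lists of mesenchymal and Schwann-like, leukocyte and epithelial markers did not pass at 5 µM, and the astrocyte and oligodendrocyte list was not tested. Mesenchymal and Schwann-like markers had a median of -0.05 over 14 genes (adjusted p = 0.423) with ANXA2 at -0.22, and all 3 treated arrays lay below all 3 untreated arrays in the list mean, with a difference of -0.08 and a 95% interval of -0.13 to -0.02. The 4 measured astrocyte and oligodendrocyte markers had a median of -0.06 with GLUL at -0.10, and 11 leukocyte markers a median of -0.04 with CD74 at -0.32. In both of these lists too all 3 treated arrays lay below all 3 untreated arrays, with differences of -0.05 (95% interval -0.10 to -0.0010) and -0.08 (-0.17 to 0.01). The median fold change over all tested probe sets was itself -0.024 at 5 µM against untreated, which these differences and intervals include. The 5 epithelial markers had a median of -0.05 with a difference of -0.07 (-0.16 to 0.02), and 2 of the 3 treated arrays lay below all untreated arrays. Of the epithelial markers 1 fell adjusted over the list alone, the transcription factor ELF3 at -0.24 ± 0.05. The gene-wise adjusted p of ELF3 was 0.208.

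**Figure D2:**
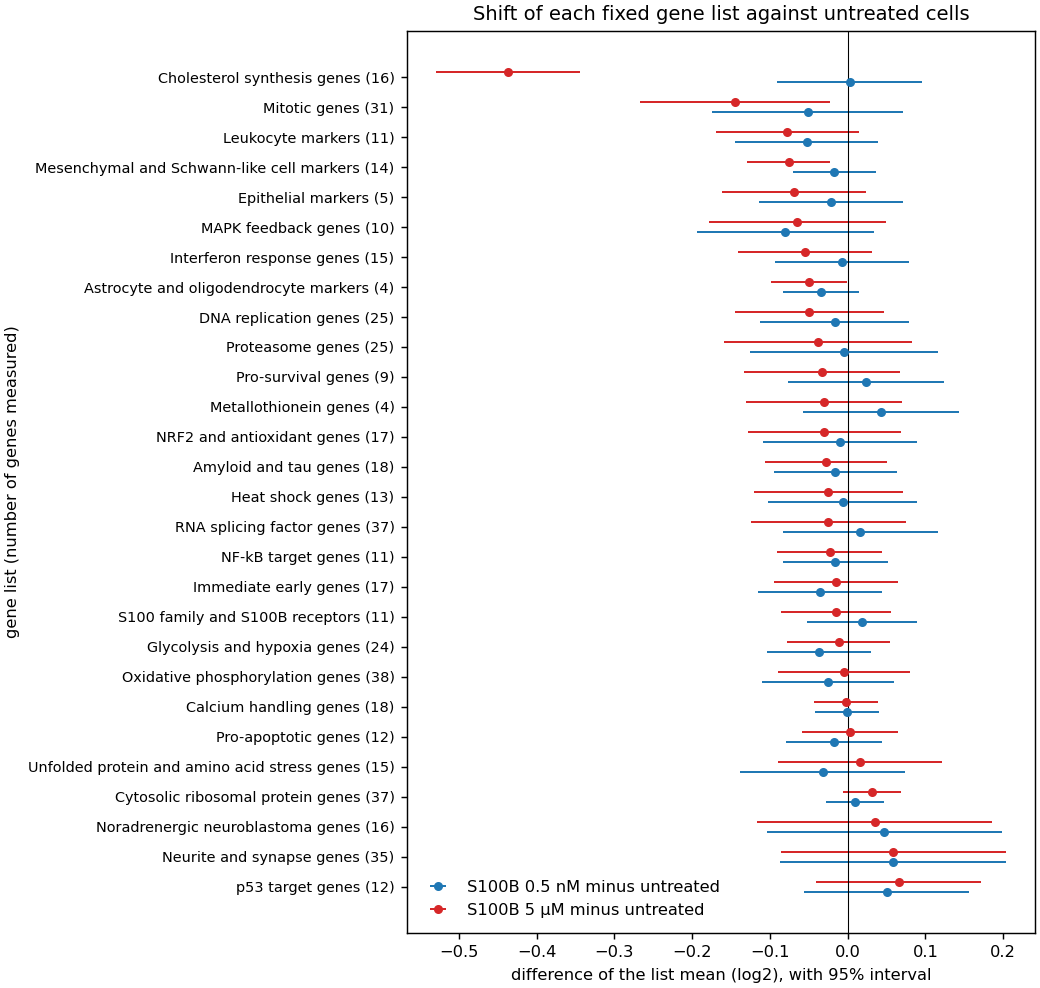
Difference of the mean of each of the 28 gene lists from untreated cells, in log2 (horizontal axis), by list with the number of genes measured (vertical axis), for 0.5 nM in blue and 5 µM in red. Points are differences of group means over 3 arrays each and bars are 95% intervals. The cholesterol synthesis list at 5 µM lies lowest, at -0.44, and at 0.5 nM it lies at 0.0027.

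The nanomolar dose was compared with untreated cells in the same fit. No gene passed: 0 of 5830 probe sets changed at 0.5 nM by limma, and 0 by an unmoderated test, while 192 probe sets (3.29%) had an unadjusted p under 0.05. The 10 genes with the smallest p did not pass (adjusted p = 0.9999) and 9 of the 10 were lower. The exception was the small GTPase RAC1, at 0.17 ± 0.05 (SE, n = 3 per group). The others were the kinases SRPK3 at -0.17 and PHKG1 at -0.20, the scaffold MPP2 at -0.21, the receptor TNFRSF13B at -0.20, the amino acid transporter SLC1A4 at -0.19, RSPH6A at -0.19, PDLIM2 at -0.19, RASL10A at -0.17 and the phosphatase INPP5E at -0.17, with standard errors of 0.05 to 0.06. The largest change of any probe set was 0.44 log2, which did not pass either.

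Cholesterol synthesis genes did not pass at 0.5 nM. Of 16 genes 0 rose or fell over all probe sets or over the list alone, the list mean differed by 0.0027 with a 95% interval of -0.09 to 0.10, and SC5D had the smallest p, at -0.15 ± 0.08. HMGCS1 was at 0.04 ± 0.12 and MSMO1 at -0.08 ± 0.09, both named after their values at 5 µM were seen. Neurite and synapse genes passed with camera's preset correlation (median 0.05, adjusted p = 0.00182) and had an adjusted p = 0.901 with an estimated correlation. The p53 targets also passed (median 0.06, adjusted p = 0.0346) and had an adjusted p = 0.863 with an estimated correlation. The list members with the smallest p were the synaptic protein SNAP25, lower at -0.22, and the DNA repair factor XPC at 0.15. The p53 list did not pass after quantile normalization (adjusted p = 0.0795) or median centring (0.0556), without 0.5 nM replicates 1 (0.281) or 2 (0.0873), untreated replicates 1 (0.11) or 3 (0.172), or replicate 3 of every group (0.0535). The neurite list did not pass without untreated replicate 2 (0.129).

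In the other lists at 0.5 nM, the member with the smallest p did not pass anywhere. In the signalling lists these were S100A10 at -0.08, CD83 at -0.17, DUSP5 at -0.18 for both immediate early and MAPK feedback genes, and CAMK4 at -0.14. Among the death and stress lists they were TNFRSF10B at 0.13, BCL2L2 at 0.11, TXN at 0.14, ERN1 at -0.25, CRYAB at -0.08 and the interferon-induced IFITM3 at 0.20. Among the growth and neuronal lists they were GINS2 at -0.09, RACGAP1 at -0.27, LMO1 at -0.15 and APOE at -0.13. In the metabolic and housekeeping lists they were PFKFB3 at 0.11, COX6A1 at -0.13, RPS3 at 0.09, PSMA4 at 0.11, the splicing regulator HNRNPL at 0.29 and MT1X at 0.20. Among markers of other cell types they were THY1 at 0.15, ALDH1L1 at -0.06, CD74 at -0.25 and ELF3 at -0.14. FGFR1 was at 0.10 ± 0.09, MYCN at 0.03 ± 0.06 and APP at -0.05 ± 0.12. Without the filter AGER was at 0.12 ± 0.05 and S100B at -0.07 ± 0.06, both with an adjusted p of 0.979.

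The doses were compared with each other to test whether they differed. Cholesterol synthesis genes fell from 0.5 nM to 5 µM and TFRC, which takes up transferrin-bound iron, rose. TFRC was 0.49 ± 0.08 log2 higher at 5 µM, at 140.3% of its level at 0.5 nM (SE, n = 3 per group, limma's adjusted p = 0.0483). HMGCS1 changed by -1.19 ± 0.12 to 43.9% of its level at 0.5 nM (adjusted p = 0.00228), MSMO1 by -0.81 ± 0.09 (adjusted p = 0.00532), and DHCR7 and SQLE by -0.68 and -0.67. LSS and INSIG1 changed by -0.61 and -0.61, CHRM3 by -0.60, HSD17B7 by -0.52, IDI1 and FDPS by -0.51 and -0.51, PPEF1 by -0.49 and the decarboxylase MVD by -0.43, all past the threshold with standard errors under those of HMGCS1.

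Of the 16 measured cholesterol synthesis genes, 9 fell between the doses, and 12 fell adjusted over the list alone. The list median was -0.47, camera's adjusted p was 3.47e-28, and the adjusted p = 0.0249 with an estimated correlation. In all 15 probe sets differed, 1 higher and 14 lower at 5 µM, with 271 at an unadjusted p under 0.05. The arrays did not overlap in 15 of the 15, against 6.98% of all probe sets and 10% by chance. Of the 14 lower, 2 do not have exactly 1 gene symbol in the annotation. The count was 5, 6 and 3 without 0.5 nM replicates 1, 2 and 3, 8 and 4 without 5 µM replicates 1 and 2, 4 without replicate 3 of every group and in a fit of only the 2 groups, and 0 with an unmoderated test. HMGCS1 and MSMO1 passed in all 9 fits that left out 1 array, while TFRC, MVD and IDI1 passed in 1 of them, INSIG1 in 2, FDPS in 4 and the other named genes in 5 to 7, each with its direction kept. TFRC and MVD did not pass after median centring (adjusted p = 0.0525 for both) or with a replicate block (0.0615 and 0.0575).

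Mitotic genes also lay lower at 5 µM than at 0.5 nM (median -0.09, camera's adjusted p = 7.37e-05), but the adjusted p = 0.901 with an estimated correlation, and it was 0.121 with the preset correlation without 5 µM replicate 1. Of 31 members 0 passed over all probe sets and 1 fell over the list alone, PLK1 at -0.29 ± 0.06. The other lists tested did not pass, with medians from -0.07 to 0.06. Among them, mesenchymal and Schwann-like markers differed by -0.06 (95% interval -0.11 to -0.0051), with 2 of the 3 arrays at 5 µM below all 3 at 0.5 nM. All 3 lay below for epithelial markers, at -0.05 (-0.14 to 0.05), and interferon response genes, at -0.05 (-0.13 to 0.04). ADM, at 0.28 ± 0.07, was the 1 member of the glycolysis and hypoxia list that rose over the list alone. In the signalling lists the members with the smallest p were ALCAM at -0.21, NFKB1 at -0.08, MYC at -0.20, DUSP6 at 0.22 and ITPR1 at 0.15. Among death and stress lists they were BAD at 0.14, BAG1 at -0.15, XPC at -0.14, PGD at -0.15, the asparagine synthetase ASNS at 0.20, HSPB1 at -0.16 and IFITM3 at -0.38. In the growth and neuronal lists they were CDC6 at -0.16, SNAP25 at 0.27, the neuropeptide NPY at -0.41 and ECE1 at -0.15. Among metabolic, housekeeping and other cell type lists they were NDUFB5 at 0.15, RPL31 at 0.18, PSMB2 at -0.11, SNRPA at -0.17, MT1X at -0.27, COL4A1 at -0.29, GLUL at -0.05, ITGB2 at -0.16 and ELF3 at -0.10. APP, FGFR1 and MYCN were at 0.10, -0.02 and 0.01, and without the filter AGER was at -0.05 ± 0.05 and S100B at -0.0084 ± 0.06. Over the 78 combinations of list and comparison that were tested, the median, the mean and the direction of the test differed in sign in 21, none of which passed.

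The probe sets that fell at 5 µM lay near untreated at 0.5 nM. Of the 17 probe sets that fell at 5 µM, 17 were lower at 5 µM than at 0.5 nM, 10 lay below untreated at 0.5 nM, and their median fold change was -0.57 at 5 µM and -0.03 at 0.5 nM. The number changed at both doses was 0. The probe sets past the threshold against untreated and against 0.5 nM shared 13, and both comparisons use the same 5 µM arrays. Across 5830 probe sets the fold changes of the doses against untreated correlated at Pearson's r = 0.476 and Spearman's rho = 0.496, across genes, which are not independent replicates. Pearson's r was 0.294 without 5 µM replicate 3, 0.294 to 0.594 over the fits that left out 1 array, with the highest without untreated replicate 3, and -0.0469 over the 17 probe sets that fell at 5 µM. Unchanged groups simulated against the same controls gave a mean r of 0.50 (0.444 to 0.547), and the observed covariance was 0.00351 against a simulated 0.00403. The simulation drew each probe set independently, so its range may be too narrow for probe sets that vary together. The same sign was found for 68.4% of probe sets against a simulated 66.6%. The 3 untreated arrays cannot be split into parts of at least 2, so no value free of the shared controls is given.

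**Figure D3:**
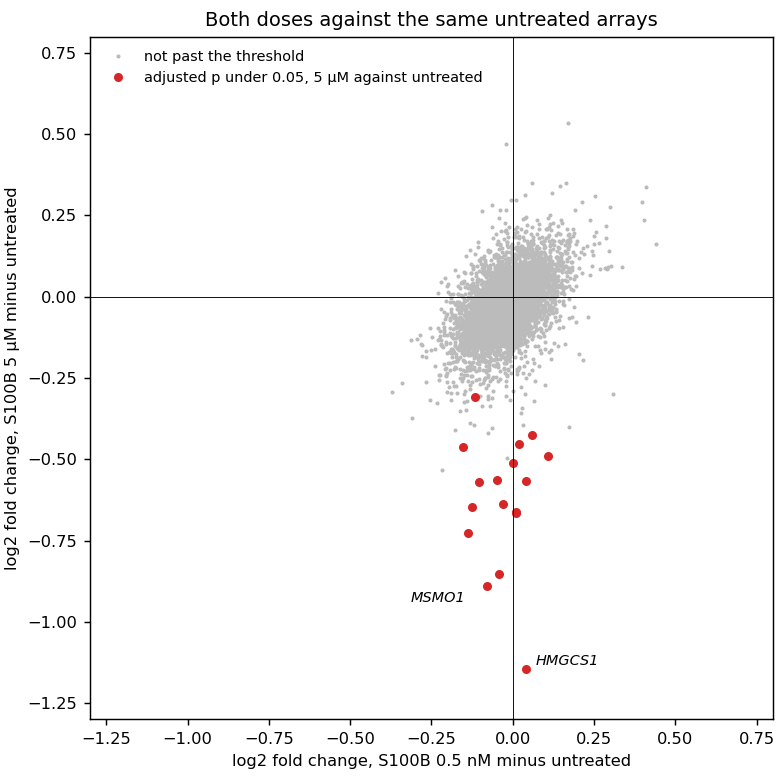
Log2 fold change of each of the 5830 probe sets at 0.5 nM (horizontal axis) and at 5 µM (vertical axis), both against the same 3 untreated arrays. Each point is a probe set, and red marks the 17 with an adjusted p under 0.05 at 5 µM. The red points spread from -1.14 upward on the vertical axis and lie within 0.153 of 0 on the horizontal axis.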

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

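The covariate of the 3'/5' control ratio, and the use of the planned fits without 1 array to look for an atypical array, were tests chosen only after the result was seen.

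In 5 µM replicate 1, a control probe set for the middle of 18S ribosomal RNA read 6.97 log2, which is 1.32 above the highest untreated array (5.65). This control is outside the main measurement. The control for the 5' end read 6.32 on that array, against at most 5.42 in untreated cells, and the one for the 3' end 7.55, against at most 6.98. Whether carry-over of ribosomal RNA shapes the comparison with untreated cells was not decided. Leaving out that array moved the median fold change of the probe sets that fell by 0.00477. Those probe sets were picked with that array included, on a low spread between arrays, so this median could hardly move. Only 6 passed without that array, where fewer arrays were fitted. The cholesterol synthesis list, set beforehand, had a median of -0.461 without that array, against -0.488 with all arrays. What raised the signal on that array stays open, and no biological explanation was tested.

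The fall of cholesterol synthesis transcripts at 5 µM was weighed against technical explanations. An atypical array as the whole cause is argued against, since the list median stayed at or below -0.443 in all 9 fits that left out 1 array, with camera's adjusted p up to 1.42e-16. The fits without a 0.5 nM array could not test this, since they left the median at -0.488. With the 3'/5' ratio of the ACTB and GAPDH controls as a covariate the median was -0.485, inside the limit set as evidence against. That covariate moved fold changes by an SD of only 0.0134, under their median standard error of 0.0704, so it tests little. The mean GAPDH ratio was 0.303 at both 5 µM (SD 0.086) and 0.5 nM (SD 0.094), and ACTB -0.008 (SD 0.130) and -0.035 (SD 0.068). The list mean still differed between these doses by -0.44 (95% interval -0.53 to -0.35). This argues against RNA integrity, as far as these controls measure it, for the fall of the list from 0.5 nM to 5 µM. Against untreated cells it was not decided. For the count of genes changed at 5 µM, the 10 splits of the 6 arrays are too few for a share under 0.05: the real split gave 17, the highest other gave 0, and 1 split, the real one, gave as many. Handling that differed between the groups was not tested, since the labels give no batch.

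The 3 arrays numbered 3 deviated together, with residual correlations of 0.298 to 0.330 between them across probe sets. Values of this size also occurred between other arrays. Between arrays of different numbers the correlations ran from -0.367 to 0.348, the highest between 0.5 nM replicate 1 and 5 µM replicate 2. RNA integrity was tested by ranking: the array numbered 3 had the highest 3'/5' ratio in its group in 5 of 6 rankings, the exception being GAPDH at 0.5 nM. With 3 arrays per group and 1 exception this stays open. The numbers do not pair the arrays in general, since 4 of 9 arrays correlated best with an array of their own number, and no biological explanation was tested.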

How the results depend on the processing

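The fit without replicate 3 of every group and the 3'/5' ratio covariate were tests chosen only after the result was seen. A pseudocount of 16 was not run, since the values are already on the log2 scale. Signal over background was not assessed.

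The count at 0.5 nM was 0 by limma in each alternative run and 0 by the unmoderated test, with 192 probe sets at an unadjusted p under 0.05. For 5 µM against untreated the count of 17 became 7 in a fit of only the 2 groups, 3 without replicate 3 of every group, 1 with a 2-fold limit and 0 in the plain test per probe set without moderation, and 4 to 17 leaving out 1 array. For 5 µM against 0.5 nM the count of 15 became 4, 4, 1 and 0 in the same order, and 3 to 14 leaving out 1 array. Fits of only 2 groups or of fewer arrays have fewer samples to estimate the spread. The plain test also used only the 2 groups compared, and it does not pool the spread over probe sets. In the other 9 alternatives the counts were 13 to 24 and 13 to 20. With the replicate block they were 15 and 15, and TFRC and MVD no longer passed between the doses, at adjusted p of 0.0615 and 0.0575.

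The lists were run under the filters, both normalizations, another probe set per gene, the replicate block, the covariate, the estimated correlation, fry and fits of fewer arrays, and not under array weights, the trended and robust prior, a fit of only the groups compared or the plain test. The cholesterol synthesis list kept its direction and its call in those run, with adjusted p up to 0.03 against untreated and 0.0249 against 0.5 nM. Leaving out 1 array gave 4.7e-23 to 1.42e-16 and 4.04e-28 to 2.28e-20. The other lists past camera's threshold kept their direction and lost the call in some alternatives, and the cause was not tested. With an estimated correlation the adjusted p was 0.863 (p53) and 0.901 (neurite) at 0.5 nM, 0.841 (p53), 0.863 (mitotic), 0.901 (neurite) and 0.901 (ribosomal) at 5 µM, and 0.901 (mitotic) between the doses. With fry it was 0.41 for mitotic genes at 5 µM and 0.826 for the others. Quantile normalization gave 0.0795 for p53 at 0.5 nM and 0.454 for ribosomal genes at 5 µM, median centring 0.0556 for p53 at 0.5 nM, and the fit without replicate 3 of every group 0.0535 for p53 at 0.5 nM and 0.175 for neurite genes at 5 µM. Leaving out 1 array gave 0.00461 to 0.281 (p53) and 3.64e-05 to 0.129 (neurite) at 0.5 nM, 0.00272 to 0.0785 (p53), 1.5e-10 to 0.00523 (mitotic), 4.19e-06 to 0.152 (neurite) and 6.37e-05 to 0.103 (ribosomal) at 5 µM, and 4.96e-07 to 0.121 (mitotic) between the doses.

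The correlation of the doses' fold changes, 0.476 across genes, was -0.0469 over the 17 probe sets past the threshold at 5 µM and 0.294 to 0.594 leaving out 1 array, and the cause was not tested. The 25 named results past the threshold kept their direction in 500 combinations with an alternative and lost the threshold in 173. The 99 named results that did not pass moved past it in 3 of 1961, and 68 list results that did not pass in 22 of 1289. The cholesterol synthesis list at 0.5 nM is not counted among the 68, and it passed in none of the alternatives run.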

Other observations

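The tests on fatty acid synthesis genes, LXR target genes and iron response genes were chosen only after the cholesterol synthesis and TFRC results were seen. They were chosen before the values of these 3 lists as a whole were seen. Members shared with the lists set beforehand could already have been seen. Among these are SREBF1, also in the cholesterol synthesis list, and ADM and VEGFA, also in the glycolysis and hypoxia list. For the counts of genes changed at 0.5 nM and between the doses, the 10 splits of the 6 arrays are too few for a share under 0.05. At 0.5 nM the real split gave 0, the highest other gave 1, and 10 splits gave as many. Between the doses the real split gave 15, the highest other gave 0, and 1 split, the real one, gave as many.

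Fatty acid synthesis genes lay lower at 5 µM. Of 19 genes 10 were measured, and adjusted over the list alone 4 fell: the desaturases FADS2 at -0.40 and SCD at -0.33, the citrate lyase ACLY at -0.32 and PCYT2 at -0.31. The hypothesis was that targets of SREBP, the transcription factors that drive both sterol and fatty acid synthesis, fell together. The median was -0.227 with camera's adjusted p = 0.00401, in line with it, but the adjusted p = 0.248 with an estimated correlation.

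Excess sterol sensed by the cells may lower cholesterol synthesis transcripts and would raise targets of LXR, a receptor for oxysterols. The 8 measured of 15 LXR targets had a median of -0.0426 (camera's adjusted p = 0.783), below 0 by more than its standard error of 0.0259, which had been set as evidence against. That limit was not decisive, since members went both ways: adjusted over the list alone MYLIP rose, at 0.18, and ABCG4 and SCD fell, at -0.19 and -0.33, and SCD and SREBF1 are also SREBP targets. The hypothesis stays open.

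TFRC, which is raised in iron shortage and hypoxia, may point to either at 5 µM. The 11 other measured iron response genes had a median of 0.0665 against 0.5 nM (camera's adjusted p = 0.126), with ADM at 0.28 and VEGFA at 0.29 but CDC42BPA at -0.24 and EPAS1 at -0.13. Of these 1, ADM, passed over the list alone and 0 over all probe sets. The glycolysis and hypoxia list was set beforehand and also holds ADM and VEGFA. Between these doses its median was 0.0155 over 24 genes (camera's adjusted p = 0.33). Neither list decided between iron shortage, hypoxia and other causes.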
